A study of Mus musculus with 2 samples.

How the data were processed

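DNase-seq was done on kidney tissue of newborn B6NCrl mice (age 0 days) in 2 libraries, per the labels biological replicates 1 and 2 of 1 group. The labels give each replicate its own tissue record and both the same donor record, and state that sex was not collected. The label of replicate 2 names a pair of Illumina sequencer models and that of replicate 1 names none.

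The authors deposited 1 list of peaks per replicate in narrowPeak format, each made from 1 alignment of 36-nt reads to assembly mm10 without alternate sequences, per the file headers, so peaks were called per sample and not on pooled samples. The aligner, the peak caller, its version and threshold, any filter and the sequencing depth are not given in the sources used here. The deposited signal value of each peak (column 7) is a multiple of 1/64, and whether the authors scaled it for depth is not given in the sources used here. The deposited −log10 p of each peak (column 8) has a maximum of 324, reached by 4026 peaks of replicate 1 and 4923 of replicate 2, and was used only to describe the lists. All peak starts lie on a grid of 20 bp. Signal values are the authors' own and were used to describe, rank and filter peaks. Log2 ratios between replicates were centred on the median of all shared sites, except for the shares and counts of peak pairs within or beyond 2-fold, which used uncentred ratios. All are descriptions, since the lists have different lengths.

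Because depth is unknown, no precision per peak can be given. Exact binomial and Poisson intervals (95%), and Wilson binomial intervals (95%) for the share of shared peaks, cover counting error only. With 1 group and 2 replicates, no test between groups exists and no p-value was computed. Values are given per replicate or as mean ± SD (n = 2).

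Peaks on chromosomes 1 to 19, X and Y were used, and none reached beyond the end of its chromosome in GRCm38, the assembly of the reference genome used here and the same build as mm10. A peak was shared when a peak of the other replicate overlapped it by at least 1 bp, and a shared site was the union of overlapping peaks that held a peak of both replicates. Chance overlap came from 100 circular shifts of 1 list along each chromosome, leaving out the first 3 Mb. Peak pairs for the correlation were peaks that overlapped 1 to 1. A site was a promoter site when its centre lay within 1 kb of any TSS of GENCODE release M21, and otherwise exonic, intronic or intergenic, in that order. A gene had a promoter peak when any peak overlapped the window of 1 kb to each side of any of its TSSs, and its promoter signal was that of the strongest such peak. A peak was called shared with another gene when it also lay within 1 kb of a TSS of another protein-coding gene. Distal counts were shared sites within 50 kb of the most 5′ TSS that were not promoter sites.

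The 22 gene lists (9 of kidney cell types, 4 of cell types that can be carried along, 8 of other tissues and 1 of ubiquitous genes), the motif list, the analyses and the rule for named genes were chosen before the data were examined. Each list was compared with 10000 random lists of protein-coding genes of equal size, and its percentile counts ties at their midpoint. For promoter peaks and distal sites, the random lists were matched on 5 quintiles of promoter CpG observed over expected (500 bp to each side of the TSS). For log2 ratios between replicates, they were matched on size only. The rule names, in each list, the 2 genes with the highest mean rank of promoter signal among those with a promoter peak in both replicates and the first 2 in alphabetical order with none in either. Six2, Wt1, Nphs1, Pax2, Pax8, Hnf4a, Slc34a1, Umod, Slc12a1, Aqp2, Gata3, Foxi1, Foxd1, Pecam1 and Alb are named whatever their values, Hox genes are given as counts by paralog group, the 10 shared distal sites with the highest mean rank are named with their nearest TSS, and so are motifs with a ratio of at least 1.5 together with HNF1, HNF4, WT1, the Six2 family and PAX2/8. Motifs below that ratio were named after their values were seen. Some genes and a motif that the rule names are not reported here, although the counts include them.

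Motifs were exact consensus matches on both strands in the central 150 bp of shared distal sites, compared with windows of 150 bp centred 500 bp to either side, and with 20 permuted forms of each consensus other than itself and its reverse complement. Further genome matches of a site were counted with blastn 2.17.0 (at least 80% identity over at least 100 bp, with no more than 200 alignments kept per genome sequence, so high counts are lower bounds). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and pysam 0.24.0, and plots were drawn with matplotlib 3.10.9.

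The steps were tested on simulated data. A simulated list with 70.3% of its peaks shared gave 70.3%, and 603 planted motif matches added 603 matches. Of 200 lists drawn at random, 4% lay outside the central 95% for a promoter measure and 5% for a median of log2 ratios. When lists were shifted by 0.5, 98% of 200 were found. That shift was planted in a single simulated value per gene and was larger than any list median of log2 ratios reported below. It does not show that shifts of the observed size, over pooled neighbouring sites, would be found.

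The alternatives were each replicate alone, the peaks in the upper 50% of signal, 50% reciprocal overlap, lists of equal length, the top 50000 peaks, autosomes only, merging of peaks within 150 bp, promoter windows of 500 bp and 2 kb, protein-coding or most 5′ TSSs, distal windows of 20 and 100 kb, a central motif window of 300 bp, flanks 1 kb away, division by the permuted ratio, promoter sites in place of distal sites, and quantile normalization of signal. For REST the median permuted ratio was 0, so it has no divided ratio and was not counted in that alternative. Another alternative, which left out genes whose promoter peak another gene shares, was chosen after seeing the data. Assembly sequences other than the chromosomes named were not used here.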

Results

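The data are lists of DNase I hypersensitive sites from the kidney of newborn mice (postnatal day 0, strain B6NCrl, a substrain of C57BL/6N). DNase I cuts nucleosome-depleted DNA, so a peak of its cuts marks accessible chromatin such as an active promoter, an enhancer or an insulator. The study holds 1 group of 2 biological replicates, replicate 1 and replicate 2, and no other tissue, age or treatment, so the comparisons are between the replicates, between parts of the genome and between gene lists. The labels give both replicates the same donor record and do not say that they came from separate animals, so the spread between them may be technical. Sequencing depth is unknown, because the peak lists hold no read counts. Coordinates are those of mouse assembly mm10.

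Replicate 1 held 266133 peaks and replicate 2 held 257133 (261633 ± 6364, SD, n = 2). The peaks covered 39.4 ± 0.960 Mb, which was 1.45% ± 0.0352 of the assembly. Of the peaks, 99.5% ± 0.00999 were 150 bp wide, the median width. Median peak signal was 17.1 in replicate 1 and 16.9 in replicate 2. Autosomes carried 104.6 ± 2.56 peaks per Mb, the X chromosome 23.2 ± 0.294 and the Y chromosome 0.365 ± 0.00771, so the gap between autosomes and X was far larger than the spread between replicates. X carried 4007 and 3936 peaks in the replicates, and Y carried 33 and 34.

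Most sites of newborn kidney were found in both replicates, and those that were not were mostly weak. In replicate 1, 198698 of 266133 peaks (74.7%, Wilson 95% interval 74.5 to 74.8) were overlapped by a peak of replicate 2. In replicate 2, 198774 of 257133 peaks (77.3%, 77.1 to 77.5) were overlapped by a peak of replicate 1. The mean of both directions was 76.0%, with an SD of 1.87 between them. Both directions are 1 comparison, so this is not a spread between independent replicates. With lists of equal length the SD was 0.0434. When 1 list was shifted along each chromosome 100 times, the overlap was 3.17% on average and ranged from 3.01% to 3.33%. The share rose with signal, from 30.8% ± 3.86 in the lowest decile of peaks to 99.1% ± 0.0407 in the highest. Unshared peaks had a median signal of 11.3 in replicate 1 and 11.2 in replicate 2, against 21.4 and 20.4 for shared peaks. Merging overlapping peaks gave 197749 shared sites that covered 35.9 Mb. The intervals cover counting error only, and the authors' peak threshold decides how many weak peaks enter each list.

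**Figure D1:**
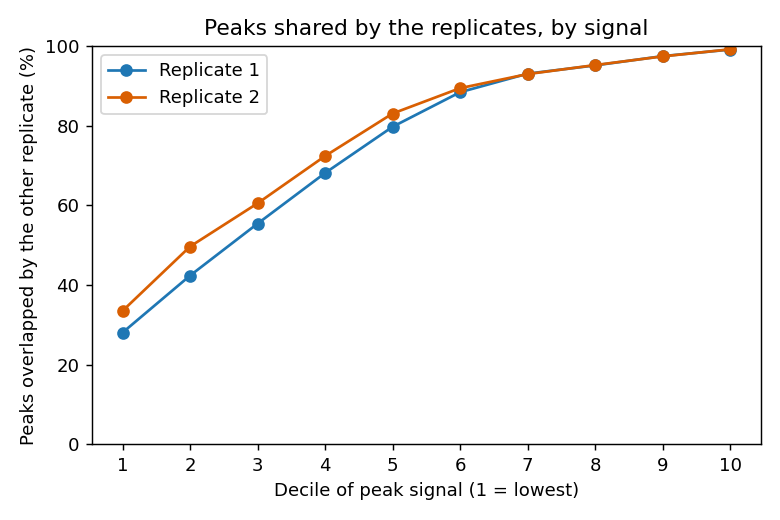
Percent of each replicate's peaks overlapped by at least 1 bp by a peak of the other replicate (vertical axis), by decile of the authors' peak signal within the replicate (horizontal axis, 1 = lowest). Blue points are replicate 1 and orange points replicate 2; the mean of the replicates went from 30.8% in the lowest decile to 99.1% in the highest.

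Signal at sites found in both replicates ranked alike. Across 195870 pairs of overlapping peaks, Spearman's rho was 0.900 and Pearson's r of log2 signal was 0.944. Taken by autosome, rho ran from 0.887 to 0.919. Of the pairs, 99.3% had signals within 2-fold of each other. Beyond that, 934 pairs were more than 2-fold higher in replicate 1 and 363 in replicate 2. These correlations are across peaks, which are not independent replicates. No p-value was computed for them, and how the authors scaled signal for depth is not given in the sources used here.

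Promoters were the part of the genome with the largest excess of shared sites. Of the 197749 shared sites, 46681 (23.6%) lay within 1 kb of an annotated transcription start site (TSS), although such windows made up 6.05% of the genome, a ratio of 3.90. Exons outside these windows held 3.92% of the sites (ratio 1.23), introns 40.3% (ratio 1.05) and intergenic sequence 32.2% (ratio 0.613). In the peaks of the single replicates, the promoter share was 22.3% ± 0.727 and its ratio to the genome was 3.69 ± 0.120 (SD, n = 2). Promoter sites also had higher signal than distal sites: the median was 31.1 against 19.8 in replicate 1 and 31.7 against 18.6 in replicate 2. Promoters made up 13.6% of the weakest decile of shared sites and 62.5% of the strongest. No test was run on these shares, since neighbouring sites are not independent.

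Genes that mark the cell types of kidney had accessible promoters more often than genes that mark other tissues. Of 99 genes in 9 kidney lists, 87 had a promoter peak in both replicates (87.9%, exact 95% interval 79.8 to 93.6), against 37 of 84 genes in 8 lists of other tissues (44.0%, 33.2 to 55.3). The difference was 43.8 percentage points, and in the single replicates it was 39.9 and 44.5 (SD 3.24). All 14 ubiquitous genes had such a peak (exact interval 76.8 to 100), led by Eef1a1, a translation elongation factor (signal 244 ± 5.80), and Tbp, the TATA-binding protein (215 ± 31.5, from a peak shared with the promoter of Psmb1). Across the genome, 15743 of 21938 protein-coding genes (71.8%) had a promoter peak in both replicates. The pooled kidney genes lay above all 10000 random lists of equal size matched on promoter CpG content, whose mean was 72.3%. The pooled other-tissue genes lay at percentile 0.04 of theirs, whose mean was 59.3%. Taken singly, only 2 of the 9 kidney lists, stroma and endothelium, lay above the central 95% of matched lists. Of the 8 other-tissue lists, 2 lay below it. Genes are not replicates, so these percentiles describe these libraries and carry no p-value.

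All genes of 5 kidney lists had a promoter peak in both replicates. They were the 9 genes of nephron progenitors, the 10 of the early nephron, the 9 of podocytes, the 13 of stroma and the 11 of endothelium. Against matched random lists, stroma stood at percentile 99.9 and endothelium at 99.7, whereas podocytes (96.6), early nephron (80.6) and nephron progenitors (70.0) lay inside the central 95%, their matched lists having means of 81.7%, 92.1% and 94.6%. Six2, the transcription factor that maintains nephron progenitors, had a promoter signal of 72.7 ± 0.376, and Osr1 had 74.6 ± 6.31. In the early nephron list, the Notch ligand gene Jag1 had 131 ± 25.3, Pax2 83.8 ± 3.93 and Pax8 62.6 ± 4.09. In the podocyte list, Wt1 had 116 ± 7.54 and Nphs1, which encodes nephrin, 71.1 ± 5.33. In stroma, the collagen gene Col1a1 had 186 ± 8.72 and Foxd1, a marker of stromal progenitors, 90.7 ± 12.6. In endothelium, Egfl7 had 64.3 ± 5.68 from a peak that also lies at the annotated gene Gm20532, the VEGF receptor gene Kdr had 63.6 ± 1.94, and Pecam1 had 23.7 ± 3.54 from a peak shared with Milr1. Each of these is the signal of the gene's strongest promoter peak (mean ± SD, n = 2).

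In the other kidney lists, some genes had no promoter peak in both replicates. Such peaks were found for 11 of 15 proximal tubule genes (percentile 92.98, mean of matched lists 56.6%), 8 of 10 genes of the loop of Henle and distal tubule (83.6, mean 67.1%), 12 of 14 genes of ureteric bud and collecting duct (75.2, mean 79.1%) and 4 of 8 genes of intercalated cells (62.3, mean 44.8%), all inside the central 95% of matched lists. No difference between kidney lists was tested. In the proximal tubule, the endocytic receptor gene Lrp2 had a signal of 45.6 ± 7.40, the water channel gene Aqp1 30.8 ± 3.90 and the transcription factor gene Hnf4a 14.8 ± 3.63, while Slc34a1, the main phosphate transporter, and Kap had no promoter peak in either replicate. In the loop and distal tubule, Calb1 had 60.8 ± 11.6, Trpm6 34.1 ± 3.03 and Umod, which encodes uromodulin, 24.0 ± 1.73. Slc12a1, the target of loop diuretics, had a promoter peak of 9.75 in replicate 2 alone, and Cldn16 had none. In ureteric bud and collecting duct, Wnt11 had 116 ± 17.1, the sodium channel subunit gene Scnn1g 58.8 ± 0.354 and Gata3 42.8 ± 3.78, while Aqp2, the vasopressin-regulated water channel, had a peak of 9.42 in replicate 2 alone. Among intercalated cell genes, Slc4a9 had 49.8 ± 8.31 and Slc26a4 22.9 ± 2.75, while Foxi1 and Atp6v1g3 had no promoter peak.

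Among other tissues, germ cell genes (2 of 10, below all matched random lists) and genes of gut and pancreas (3 of 13, percentile 0.06) had the fewest promoter peaks relative to matched random lists. Liver had the lowest share, 2 of 11 (18.2%, percentile 4.02). Eye had 4 of 10 (11.2), lung 3 of 8 (23.0) and epidermis 3 of 8 (44.0), while muscle had 9 of 12 (87.8) and neuron 11 of 12 (87.0). Alb, Ahsg, Myh1, Myh4, Scgb1a1, Scgb3a2, Cdx1, Cpa1, Dsg3, Flg, Crx, Cryaa, Ddx4 and Dppa3 had no promoter peak in either replicate. Some genes of these lists did have strong promoter peaks. Actn3 had 183 ± 10.8 from a peak shared with Zdhhc24, Dazl 119 ± 0.486, Krt10 118 ± 3.89, Opn1sw 76.8 ± 14.1, Snap25 75.6 ± 6.93, Gnat1 59.9 ± 5.07, Ckm 51.5 ± 9.39, Apob 49.3 ± 9.56, Rbfox3 47.2 ± 1.61 and Cela1 45.9 ± 4.87. Lower values stood at Pou5f1 (39.8 ± 4.49), Krt1 (32.9 ± 1.25), Fgb (21.4 ± 8.18), Atoh1 (19.3 ± 0.442), Ager (16.4 ± 0.685) and Nkx2-1 (11.9 ± 1.20).

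Cell types that a kidney dissection can carry along had promoter peaks in 14 of 35 genes (40.0%, exact interval 23.9 to 57.9), at percentile 29.8 of matched random lists, whose mean was 44.0%. Leukocyte genes had a promoter peak in both replicates in 3 of 10 cases (percentile 15.6), erythroid genes in 4 of 9 (54.8), adrenal cortex genes in 4 of 10 (60.9) and genes of neural crest and nerve in 3 of 6 (42.0). The leukocyte factor Spi1 had 12.9 ± 1.56 and Laptm5 12.1 ± 2.02, while the macrophage genes Adgre1 and C1qb had none. Among erythroid genes, the erythropoietin receptor gene Epor had 59.4 ± 5.90, while Alas2 and Gata1, both on the X chromosome with its lower peak density, had none. In adrenal cortex, Cyp17a1 had 42.6 ± 0.475 and Star 40.2 ± 0.442, while Cyp11b1 and Cyp11b2 had none.

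**Figure D2:**
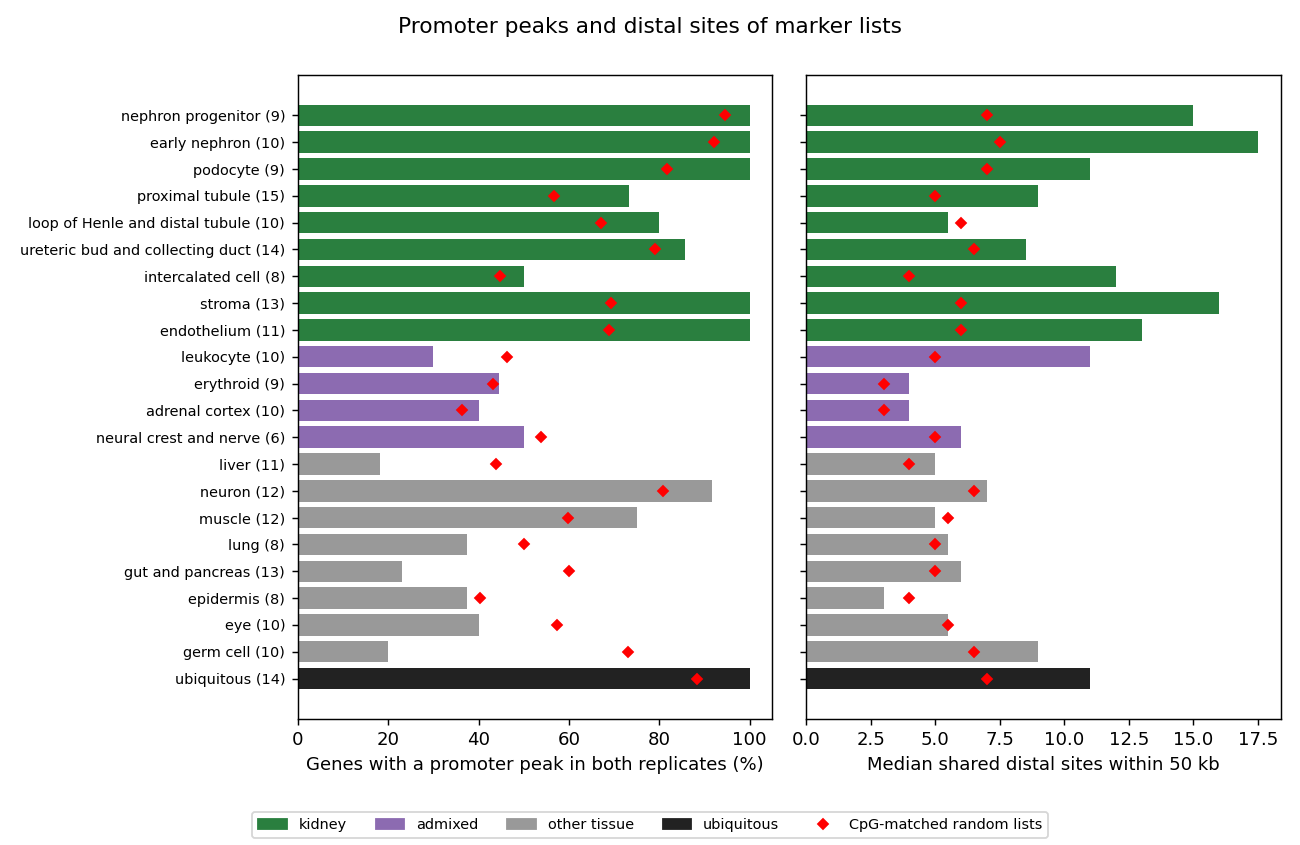
Left, percent of the genes of each list with a promoter peak in both replicates; right, median number of shared distal sites within 50 kb of the genes. Bars are the lists (gene number in brackets) coloured by class, and red diamonds are the mean (left) and the median (right) of random lists matched on promoter CpG content; stroma and endothelium lie above their diamonds on both sides.

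Promoter peaks of Hox genes, which set position along the body axis, were counted by paralog group. All 27 genes of groups 1 to 9 had one in both replicates, as did all 3 genes of group 10 and all 3 of group 11, whose genes are needed for the metanephric kidney. In group 12 it was 1 of 2 genes and in group 13 it was 2 of 4. Most Hox genes lie in the upper quintiles of promoter CpG content, where nearly all genes had a peak. In replicate 1 the share of autosomal genes was 91.7% in quintile 3 and 99.3% in quintile 5, the highest. Full shares in a group therefore do not set Hox genes apart. Over the genes of groups 1 to 9, the median percentile of promoter signal among all peaks of the replicate was 96.9. It was 98.5 for group 10 and 93.7 for group 11. Over the genes with a peak in both replicates, it was 80.5 for group 12 and 76.2 for group 13. These groups hold few genes, and single genes departed from this order: Hoxc13 had a signal of 88.0 and Hoxc11 29.8. Promoter sites had higher signal than distal sites, so these are not ranks among promoters. Some Hox genes share a promoter window, so these counts are not independent.

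Kidney genes were also surrounded by more distal sites. Within 50 kb of the TSS, genes of the kidney lists had 12.4 ± 7.77 shared distal sites (SD over 99 genes) and genes of the other-tissue lists had 7.27 ± 5.48 (SD over 84 genes), a ratio of 1.71. The ratio was 1.75 in replicate 1 and 1.67 in replicate 2 (SD 0.0587, n = 2). The median was 17.5 for the early nephron and 16 for stroma (both at percentile 99.995 of matched random lists), 15 for nephron progenitors (99.4), 13 for endothelium (99.3) and 12 for intercalated cells (99.4), so 5 of 9 kidney lists lay above the central 95%. With the peaks in the upper 50% of signal, endothelium fell inside it (percentile 96.3) and podocytes stood at 67.2. Podocytes had 11 (94.7), proximal tubule 9 (94.8), ureteric bud and collecting duct 8.5 (82.8), and loop of Henle and distal tubule 5.5 (40.0). Of the admixed lists, leukocytes had 11 (98.5), also above the central 95%, and stayed above it with the peaks in the upper 50% of signal (98.5). Neural crest and nerve had 6 (66.2), adrenal cortex 4 (67.0) and erythroid cells 4 (58.1). None of the 8 other-tissue lists lay outside the central 95%: germ cell had 9, neuron 7, gut and pancreas 6, lung and eye 5.5, liver and muscle 5, and epidermis 3. Ubiquitous genes had 11 (96.6).

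By gene, distal sites and promoter peaks did not always go together. Jag1 had 29 shared distal sites, Foxd1 24, Pax2, Pax8 and Wnt11 22, and Six2 20. Foxi1 had 12 and Aqp2 had 11 although neither had a promoter peak in both replicates. The Six2 locus (chromosome 17, gene at 85684277 to 85688274) held 39 and 34 peaks within 50 kb in the replicates, and the Wt1 locus (chromosome 2, 105126529 to 105173616) held 38 and 40. The Alb locus (chromosome 5, 90460897 to 90476602) held 13 in each, although Alb had no promoter peak. The highest was upstream of Alb in replicate 1 (90458861 to 90459010, signal 49.95) and inside the neighbouring gene Afp in replicate 2 (90500841 to 90500990, 44.6). A site within 50 kb of a gene is not shown to act on it.

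**Figure D3:**
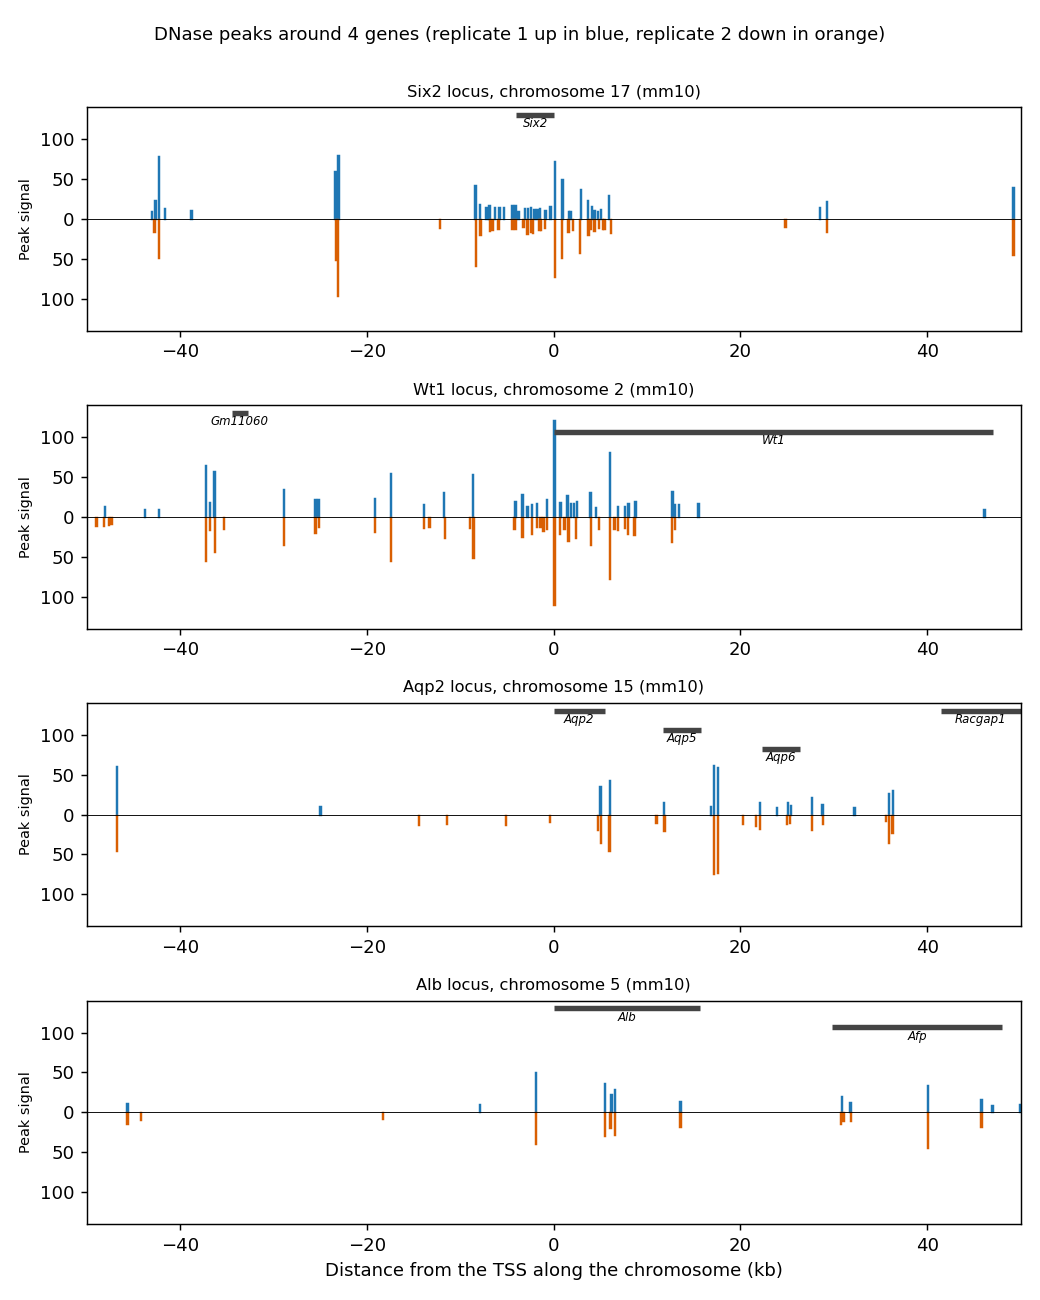
DNase peaks within 50 kb of the TSS of Six2, Wt1, Aqp2 and Alb (horizontal axis, distance from the TSS in kb along the chromosome, mm10), with peak signal on the vertical axis. Blue bars pointing up are peaks of replicate 1, orange bars pointing down are peaks of replicate 2, and grey bars are protein-coding genes; Six2 and Wt1 hold 34 to 40 peaks per replicate and Alb holds 13.

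For the 10 strongest distal sites, the nearest TSS was mostly that of a predicted gene or pseudogene, at up to 35535 bp. How often this holds for other distal sites was not computed. The site with the highest mean rank, on chromosome 9 at 35305361 to 35305530 in an intron and 2153 bp from the TSS of the long noncoding RNA Gm33838, had a signal of 2160 in replicate 1 and 6022 in replicate 2. Next came an intergenic site on chromosome X (143482981 to 143483130), 35535 bp from Pak3, with 547 and 2037. A site on chromosome 2 (98665061 to 98665230), 2155 bp from Gm10800, had 623 and 1310, and a site on chromosome 14 (19417761 to 19417910), 1094 bp from Gm21738, had 493 and 781. The other 6 lay near Cdk8 (chromosome 5, 146261141 to 146261310), Gm11668 (chromosome 11, 109011861 to 109012010), Gm2651 (chromosome 6, 3201421 to 3201570), CR555305.2 (chromosome 19, 61266581 to 61266730), Gm25352 (chromosome 3, 5860621 to 5860770) and Gm10715 (chromosome 9, 3035761 to 3035930), with signals of 341 to 504 in replicate 1 and 449 to 803 in replicate 2. Of these 10 sites, 5 had 10 or more further matches in the genome, against 3% of 300 randomly drawn distal sites.

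Consensus matches of CTCF, REST and several transcription factors of the kidney were more frequent at the centres of distal sites than in their flanks. So were those of MyoD, PU.1 and MEF2. Few distal sites held a given match: 3.89% for CTCF, 0.361% for HNF4, 0.276% for WT1, 0.197% for REST and 0.0708% for HNF1. Of 30 consensus motifs scanned at 151068 shared distal sites, 20 had at least 1.5 times as many matches per site in the central 150 bp as in flanks 500 bp away. REST, a repressor of neuronal genes, had the highest ratio (121, exact 95% interval 51.2 to 375, from 302 central and 5 flank matches), followed by the insulator protein CTCF (34.8, 31.2 to 38.9). HNF1 had 5.47 (3.86 to 7.87) and WT1 had 4.93 (4.12 to 5.93). The motif of Six2 and its relatives had 2.05 (1.92 to 2.19), HOX9-11 1.95 (1.86 to 2.05), TFCP2L1 1.93 (1.64 to 2.27), HNF4 1.70 (1.51 to 1.91) and PAX2/8 1.65 (1.52 to 1.79). NFI had 11.0, RFX 5.76, ETS 2.76, the E-box of MyoD 2.51, NRF1 2.38, TEAD 2.31, PU.1 2.25, MEF2 2.13, AP-1 1.84 and SP/KLF 1.73. Ratios in single replicates were 105.7 and 104.3 for REST, and, as mean ± SD (n = 2), 25.4 ± 0.793 for CTCF, 5.44 ± 0.140 for HNF1, 4.18 ± 0.156 for WT1 and 1.91 ± 0.00227 for Six2.

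Fewer motifs stood out against their own base composition. Of the 20 motifs, 15 had a ratio above every one of 20 permuted forms of the same consensus. The Six2 motif (highest permuted ratio 2.10), PAX2/8 (2.53), TFCP2L1 (3.33) and NRF1 (3.50) were among those that did not. GATA (0.875, 0.836 to 0.916), ESRR (0.891), CRX/OTX (0.915) and OCT (0.919) had fewer matches at the centre than in the flanks, each with an interval below 1. FOX (1.43), TFAP2 (1.42), NeuroD (1.37), RUNX (1.27), TCF/LEF (1.15) and SOX (1.08) lay between. GATA (permuted 0.497 to 1.24), ESRR (0.308 to 1.58), CRX/OTX (0.420 to 1.89) and OCT (0.577 to 1.76) lay inside their permuted ranges. The lower ratios of GATA, ESRR, CRX/OTX and OCT therefore do not show depletion beyond what base composition gives. GC content was 48.3% at the centre and 45.1% in the flanks, and a consensus match does not show that a factor was bound.

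**Figure D4:**
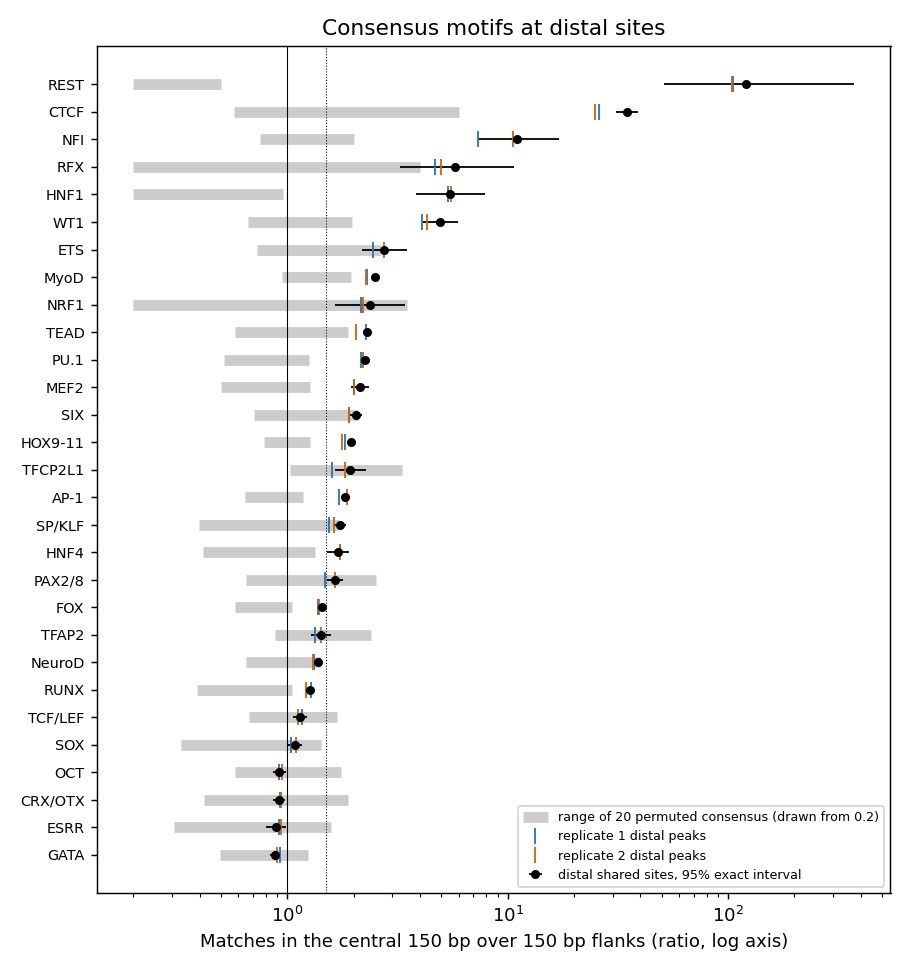
Ratio of consensus matches in the central 150 bp of shared distal sites over flanks of equal width (horizontal log axis) for the motifs reported. Black points with bars are ratios with exact 95% intervals, blue and orange ticks are the replicates' own distal peaks, grey bars are the range of 20 permuted forms (drawn from 0.2 upward), and lines mark ratios of 1 and 1.5; REST (121) and CTCF (34.8) lie farthest to the right and GATA (0.875) farthest to the left.

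The replicates differed little in the signal around marker genes. Of 22 lists, only proximal tubule lay outside the central 95% of random lists of equal size, which were not matched on CpG content. Its median log2 ratio of replicate 2 over replicate 1 was -0.09 over 203 shared sites within 50 kb of its genes (percentile 1.41). Among distal sites this ratio rose with GC content, which the random lists did not control for. By chance, 1.1 of 22 lists are expected outside. The medians of the other lists ran from -0.06 for loop of Henle and distal tubule to 0.09 for liver. Nephron progenitors stood at -0.000165, podocytes at -0.00610, endothelium at 0.07 and stroma at -0.05. This call was lost in 2 alternatives. With the peaks in the upper 50% of signal, proximal tubule stood at percentile 46.9, and lung (-0.14) and epidermis (-0.23) lay outside. With sites within 100 kb, it stood at 14.1, and ureteric bud and collecting duct (0.07) and epidermis (0.10, of opposite sign) lay outside. With 1 library on each side and an unstated scaling of signal, these values describe the libraries and not a difference in cell make-up.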

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

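The alternative that left out genes whose promoter peak another gene shares was chosen after seeing the data; it gave a difference of 44.9 percentage points between kidney and other-tissue lists, within the spread between replicates. Of 43 alternatives over 8 results, 23 stayed within a bound and 20 moved beyond it. The bound was the spread between replicates (for the shared share, between both directions; for rho, between autosomes). For numbers of motifs and lists it was 1.5 times. Some outcomes were fixed by the bound, so the tally is not a measure of robustness. For peak number, either replicate alone always lies within the spread around their mean. For lists that differed between replicates, any count other than 1 lies beyond it. Only rho and the difference in promoter peaks between lists could have turned direction, and neither did. The other measures cannot fall below 0, so no turn could be found in them. With the peaks in the upper 50% of signal, the mean number of peaks was 130706, the shared share 83.7%, the promoter share 30.6% and the number of lists that differed between replicates 2 (lung and epidermis); the peak number follows from the setting, and the cause of the others was not tested. Merging peaks within 150 bp left 243622 peaks. The shared share was 67.3% with 50% reciprocal overlap and 87.3% among the top 50000 peaks, and rho was 0.910 with 50% reciprocal overlap. The promoter share was 17.01% with a window of 500 bp, 30.8% with 2 kb and 20.2% with protein-coding TSSs alone, as narrower or fewer windows hold fewer sites; using the peaks of either replicate alone gave 21.8% to 22.8%. The difference between kidney and other-tissue lists was 53.9 points with 500 bp, 30.6 with 2 kb and 47.5 with the most 5′ TSS, and 39.9 to 44.5 with either replicate alone; the cause was not tested. The ratio of distal sites was 2.23 within 20 kb and 1.43 within 100 kb, and 2 lists differed between replicates with 100 kb (ureteric bud and collecting duct, and epidermis); proximal tubule, which differed otherwise, was in neither pair, and the cause was not tested. The number of motifs at or above 1.5 ranged from 14 at promoter sites to 20. Depth is unknown, so which weak sites were missed in each replicate is open.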

Other observations

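The gene families, the count of genes with the most distal sites, the sex-linked genes, the signal ranks of motifs, the comparison of the strongest sites between replicates, the promoter signal ratios of X and the tests that joined explanations for it were chosen after the data were seen. Of 1093 olfactory receptor genes, 19 had a promoter peak in both replicates (1.74%, against 24.6% in random lists matched on promoter CpG content), and of 327 vomeronasal receptor genes, 2 had one (0.612% against 22.8%). Clustered protocadherin genes had 22 of 57 (38.6% against 83.1%) and keratins 15 of 49 (30.6% against 59.8%). Solute carriers, many of which work in tubule transport, had 286 of 342 (83.6% against 76.1%, above all 2000 random lists), and Fgf ligands 21 of 22 (95.5% against 78.9%, percentile 99.1). Wnt ligands had a mean of 14 distal sites per gene, against 8.19 in matched lists, which was above all 2000, but their promoter peaks (89.5% against 86.3%, percentile 66.1) did not stand out. In all, 15 families were examined; 2 lay above and 5 below the central 95% of random lists for promoter peaks, and 2 above and 3 below for distal sites, where chance puts 0.75 outside for each. How well 36-nt reads map to such duplicated genes was not tested.

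Sites with a CTCF match had a median signal at percentile 85.8 of distal sites, those with REST at 75.6, NRF1 at 74.7, SP/KLF at 65.6 and WT1 at 60.2, while those with HNF4 lay at 40.3 and HNF1 at 45.5. The genes with the most shared distal sites within 50 kb were Bahcc1 (52), Trim8 (45), Ccdc85c (41), Hoxb5 (40) and the adjoining basement membrane collagen genes Col4a1 and Col4a2 (39 each), followed by Tgm2, Irf2bpl and Tgfbi (38 each). On the Y chromosome, the promoters of Ddx3y (58.8 and 37.0 in the replicates), Eif2s3y (40.6 and 30.2), Kdm5d (50.7 and 38.1) and Uty (44.2 and 37.9) had peaks in both replicates, and so did the promoter window of Xist on X (38.8 and 45.0). The X-linked counterparts Ddx3x (91.5 and 104.6), Eif2s3x (67.1 and 87.3), Kdm5c (140.6 and 188.6) and Kdm6a (153 and 224) also had promoter peaks in both. Every Y promoter named was thus lower in replicate 2, and every X promoter named, with Xist, was higher. The labels give no sex for either tissue sample, and whether the mix of sexes differed between them was not tested.

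The 10 strongest distal sites had higher signal in replicate 2, with a median centred log2 ratio of 0.66, outside the range of -0.00443 to 0.25 in random sets of 10 from the 1000 next strongest sites. This comparison restates what was seen and decides nothing about its cause. Their median number of further genome matches was 10, against 0 for random sets of distal sites, so reads of high-copy repeats piled up on few assembled copies may account for part of them. It does not reach the site near Gm11668, which had 0 further matches. Differences in depth, library or sequencer between the replicates were not tested and stay open, and no biological explanation was tested.

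The X chromosome carried 23.4 and 23.0 peaks per Mb in the replicates, below every autosome (88.4 to 145 and 84.0 to 142), and also per protein-coding gene (4.19) and per Mb of unmasked sequence (45.6), which argues against gene number or repeats as the whole cause. Halving autosomal signal in a simulation left 37.1 peaks per Mb on the lowest autosome (mean of the replicates, 38.4 and 35.8), 58.6 per unmasked Mb and 3.53 per gene, of which only the last was under X, through chromosome 7 alone. The bound set beforehand for halving was wrong as a way to exclude a single accessible copy, because it rests on an assumed threshold, so that copy may contribute, alone or with these factors, and stays open. Promoter peaks on X had lower median signal than autosomal ones in all 5 quintiles of promoter CpG content (0.519 to 0.802 and 0.462 to 0.909 times), and fewer X genes had a peak, from 94.9% against 98.3% in quintile 4 to 25.9% and 24.6% against 58.9% and 59.4% in quintile 2. Mapping of 36-nt reads on X was not tested and stays open. The labels do not give the sex of the tissue. Promoter peaks at Ddx3y, Eif2s3y, Kdm5d and Uty in both replicates (signals of 30.2 to 58.8) argue against tissue from females alone. Whether female tissue was also present, and whether its share differed between the replicates, was not tested and stays open.

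Promoter sites were relatively stronger in replicate 2 than distal sites, by 0.12 in the median log2 ratio of replicate 2 over replicate 1, in all 19 autosomes. Matching sites on signal left 0.084, at least 50% of the difference in 19 of 19 autosomes, which argues against different scaling of strong and weak sites as the whole cause. Matching on GC content left 0.060, at least 50% of it in 10 autosomes and less in 9, so an effect of GC content as the main cause cannot be told apart from a difference between promoters and distal sites themselves. Among distal sites, the ratio went from -0.16 in the lowest decile of GC content to 0.09 in the highest. A GC-dependent difference between libraries may contribute, no biological explanation was tested, and the sequencer models named for replicate 2 alone keep a technical difference open.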
